A study of Mus musculus with 4 samples.

How the data were processed

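Pooled whole molar germs of C57BL/6 mouse embryos were profiled at E11, E12, E14, E16 and E18. Per the labels, total RNA was extracted with Trizol, E14 RNA was labelled with Cy3 and the RNA of the other stage with Cy5, and each array held 1 such pair. How many germs or litters made up a pool is not given in the sources used here. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 10.5.1.1, and the deposited scanner files hold linear intensity values per spot (mean signal and median background of each channel) together with flags. Per the file headers, the deposited LogRatio column is a log10 ratio of Cy5 over Cy3 from the software's background-subtracted, dye-normalized signals. The deposited series value table holds log10 ratios too: 100% of its values on each array matched LogRatio within rounding, its column medians were 0, and scale and direction were thereby settled, with no further centring found. Submitters' processing notes name Agilent Feature Extraction, without a version.

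From the deposited intensity values, log2 ratios were computed with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) on mean signals and median backgrounds, and each array was normalized by intensity-dependent loess with control spots at weight 0. Control spots and spots with outlier flags (92 to 126 per array) were left out, and no spot was saturated. Spots of a probe were averaged. The offset pulls ratios of dim genes towards 0: the median mean signal was 39.8 to 44.0 in Cy3, over a median background of 15.0 to 17.0, and 51.5 to 71.7 in Cy5, over 31.0 to 33.5. Log2 ratios of dim genes are therefore compressed. Spike-in controls gave a slope of observed over designed log ratios of 0.932 to 0.947 per the file headers. Over 180 probes with 10 spots each, the SD between spots had a median of 0.05 to 0.06 log2 units.

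Of 41174 probes, 22951 were named by accession through a RefSeq gene table (assembly GRCm38.p6, used for names only), 6659 by symbol and 3109 by synonym, and 8455 kept the array's name. A gene took the value of its probe with the highest mean signal over the 4 arrays, and counted as measured if that probe was well above background in Cy5 on at least 1 array or in Cy3 on at least 2. Probes of the same gene each at least 2-fold from E14 in opposite directions occurred in 1 of 6116 genes with several measured probes, at E18. Where a gene was not well above background in 1 channel, a bound is given: the bright channel against the higher of the lowest signal among probes well above background and the dim channel's own, per channel after loess and Aquantile, open to dye bias. Coordinates are those of the scanner files, build mm7 per the file headers.

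Genes at least 2-fold apart were counted on each array and between arrays with no test. A linear trend in embryonic day was fitted to the 4 arrays with limma's lmFit and eBayes with an intensity trend, with Benjamini-Hochberg adjustment over 17414 genes. For 26 gene lists, camera (preset correlation 0.01) tested the slope, with adjustment over lists, beside camera with an estimated correlation and fry, and each list's median per array was placed among 10000 random lists matched on mean signal in 20 bins. With a preset correlation 16 lists passed, 12 up and 4 down, and with an estimated correlation none did. The preset p-values measure spread over genes, not over pools, and take the genes of a list as nearly uncorrelated. The estimated correlation was highest for the keratinizing list (0.82) and epithelial keratins (0.74). It was below 0 for the ameloblast (-0.053), BMP (-0.053) and Notch (-0.062) lists, so a high correlation is not why those failed. The test with an estimated correlation rests on 2 residual degrees of freedom, so it has little power and a failure there decides little. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named, per array, the 5 highest and 5 lowest genes among those well above background in both channels and the 3 largest bounds each way, the 8 largest slopes each way, up to 3 members at either end of each list described, and a fixed set of markers. A gene named outside this rule was chosen after its values were seen. Of the alternatives, 1, which leaves out the keratin lists, was added after the data were seen.

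The slide was read from the file headers. E11 and E12 shared 1 slide, E16 and E18 the other, so slide follows the stage side of E14. It was fitted as a block, for the lists only with camera's preset correlation. The trend step was tested on simulated data on all 17414 genes with 200 genes given known slopes: 59.7% of those with a slope of 0.2 per day, 98.5% at 0.4 and 100% at 0.8 were called, with 1 false call. The simulated noise was independent between genes and arrays and held no slide effect. The 1 false call therefore does not bear on calls that slide could cause. Alternatives were no background correction, scanner log ratios, series table values, median centring, the mean of all probes, other filters on dim probes, scaling between arrays, stage as a rank, 2 arrays against 2, no intensity trend, each array left out, and slide as a block.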

Results

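Whole molar tooth germs of C57BL/6 mouse embryos were profiled at 5 stages, embryonic day (E) 11, 12, 14, 16 and 18. In the mouse lower molar these days run from the early thickening of the dental epithelium, through the bud and the cap (around E14), to the bell, when the cells that will make dentin and enamel differentiate. Pooled germs of E11, E12, E16 and E18 were each hybridised, in the Cy5 channel, with pooled germs of E14 in the Cy3 channel, on 1 two-colour oligonucleotide array per stage, 4 arrays in all. E14 was therefore measured 4 times and each other stage 1 time. The dyes were not swapped. Positive log2 ratios below mean a higher level in the named stage than in E14. Of 41174 probes, between 52.5% (E18) and 59.0% (E12) were well above background in Cy5, and between 54.3% and 57.0% in the E14 channel, and 17414 genes were measured in at least 1 stage. The E14 channel repeated closely: its SD over the 4 hybridisations had a median of 0.04 log2 units over genes (95th percentile 0.09), and between 0.0287% and 0.0459% of genes differed by 2-fold or more between any pair of E14 hybridisations. That spread is technical. With 1 pool per stage there is no biological replicate, the number of arrays limits the precision, and no p-value is given for any single array.

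At E11, the early stage before a bud has formed, an embryonic globin gene stood highest above E14, and the lists of epithelial keratins and of mesenchymal matrix lay below E14. The embryonic beta-like globin Hbb-bh1 was 22.4-fold higher than at E14 (log2 ratio 4.49; SD of E14 0.09, n = 4), followed by Asb4 (3.52), Car14, a membrane carbonic anhydrase (3.02), Fgf8, the epithelial signal that starts tooth formation (2.96), and Smoc1 (2.73). The lowest were Col8a1, a short-chain collagen (-4.83), the calcium-binding protein gene S100a4 (-4.58), the epithelial serpin Serpinb5 (-4.41), the potassium channel gene Kcnj8 (-4.29) and Col6a3, a collagen VI chain (-4.24). Among genes not well above background in 1 channel, Hemgn, an erythroid nuclear protein, was at least 4.70-fold higher at E11, Agtr1a at least 3.65-fold and Tbx18 at least 2.61-fold. Egr2, an immediate early transcription factor, was at least 14.2-fold lower, Calca at least 6.13-fold and Rerg at least 5.28-fold.

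At E11, 1126 genes were at least 2-fold apart from E14, 278 higher and 848 lower. The list of 29 epithelial keratins and junction genes had a median log2 ratio of -1.59, at percentile 0 of 10000 random lists matched on mean signal, and the 26 mesenchymal matrix genes one of -1.59, also at percentile 0. Mitosis and DNA replication genes (36 measured) lay above E14, with a median of 0.51 at percentile 100. The scanner software's own log ratios, which carry no added offset, gave 3854 genes, 40.0% of them higher against 24.7% here. Median centring in place of the intensity-dependent loess moved the median of all genes to 0.40 at E11, 0.64 at E12, 0.57 at E16 and 0.17 at E18 and gave 4556 genes at E11, 93.7% of them higher.

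At E12 the highest gene was again Hbb-bh1. It stood at 2.93, Asb4 at 2.62, Fgf8 at 2.58, the metalloprotease gene Adamts15 at 2.03 and the embryonic alpha-like globin Hba-x at 1.98. Kcnj8 (-4.48), Egr2 (-4.18), the procollagen N-proteinase gene Adamts2 (-3.68), Serpinb5 (-3.61) and S100a4 (-3.48) were the lowest. As bounds, Agtr1a was at least 2.07-fold higher, Fam155a at least 1.93-fold and Pax3, a neural crest and muscle precursor factor, at least 1.90-fold, while Egr3 was at least 5.94-fold lower, the adipokine-family gene C1qtnf3 at least 5.19-fold and Omd, the matrix protein osteomodulin, at least 3.66-fold. In all 513 genes were at least 2-fold apart from E14, 55 higher and 458 lower. Scanner log ratios gave 2252 (38.0% higher against 10.7%) and median centring 5790 (97.8% higher).

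**Figure D1:**
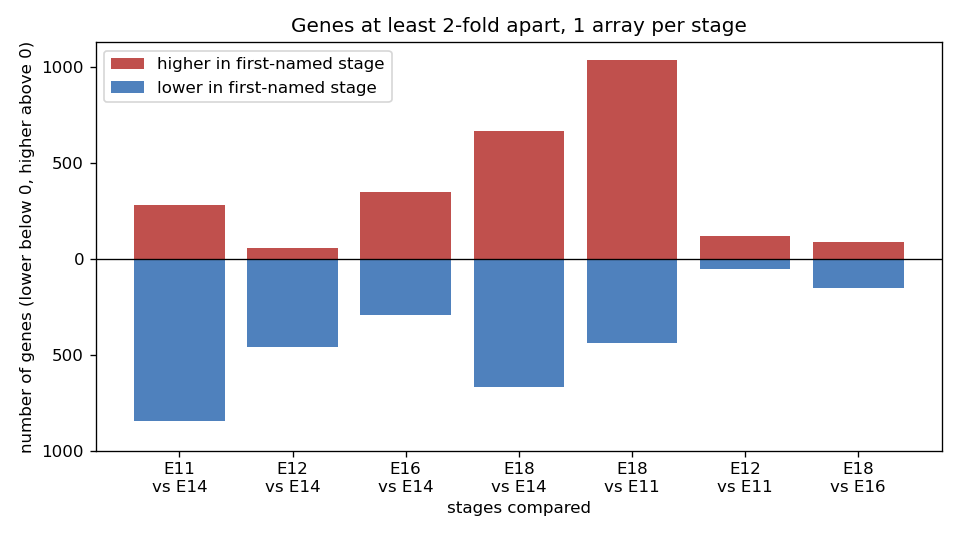
Number of genes at least 2-fold apart in each comparison (y axis, genes higher in the first-named stage above 0 and genes lower below 0; x axis, stages compared; 1 array per stage, so no error bars). E11 and E12 had more genes below E14 (848 and 458) than above it (278 and 55), and E18 had 663 above and 671 below.

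At E16 genes of stratified, keratinizing epithelium were among the highest. Spink5, a protease inhibitor of the epidermis, was 14.7-fold higher than at E14 (3.88; SD of E14 0.02, n = 4), followed by Ly6d (3.77, with an SD of E14 of 0.30), Nts, the neuropeptide neurotensin (3.09), Krt16, a keratin of activated epithelium (2.99), and Krt1, a suprabasal keratin (2.96). The embryonic globins were the lowest, Hbb-y at -6.03, Hbb-bh1 at -3.79 and Hba-x at -2.99, then the tendon factor Scx at -2.77 and Prrx1, a homeobox factor of jaw mesenchyme, at -2.72. As bounds, Mmp13, a collagenase of bone and cartilage turnover, was at least 6.61-fold higher, Plekhs1 at least 5.48-fold and Cyp2f2 at least 4.97-fold. Afp was at least 2.46-fold lower, Zpld1 at least 1.58-fold and Fxyd7 at least 1.54-fold. The keratinizing oral epithelium list (15 measured) had a median of 1.41 at percentile 100, with 10 members at least 2-fold above all 4 other stages.

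In all 644 genes were at least 2-fold apart between E16 and E14, 349 higher and 295 lower. Of the genes, 35 were at least 2-fold above all other stages at E16. Scanner log ratios gave 2883, and median centring 4297 with 99.0% higher against 54.2%.

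At E18, when ameloblasts and odontoblasts differentiate, the highest genes were Plac8 (39.3-fold, log2 5.30; SD of E14 0.04, n = 4), Plekhs1 (4.29), the phospholipase A2 receptor gene Pla2r1 (4.23), Shh, the hedgehog signal of the dental epithelium (4.03), and Krtap17-1, a keratin-associated protein (3.94). Hbb-y was 138-fold lower (-7.11), followed by Prrx1 (-3.92), the retinoic acid hydroxylase gene Cyp26b1 (-3.74), Erdr1 (-3.72) and Fibin (-3.65). Mmp13 was at least 8.04-fold higher, Serpinb12 at least 7.70-fold and Fabp4, the fatty acid binding protein of fat and vessels, at least 5.86-fold. Hbb-bh1 was at least 15.6-fold lower, Dmrt2 at least 4.89-fold and Egr3 at least 3.98-fold. Of the genes, 1334 were at least 2-fold apart from E14, 663 higher and 671 lower. Scanner log ratios gave 4513, and median centring 2310 with 87.5% higher against 49.7%.

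Differences between stages other than E14 were read through the shared reference, in which a dye effect common to both arrays cancels. Between E18 and E11, 1472 genes were at least 2-fold apart, 1032 higher at E18 and 440 lower. Within the pair of arrays on the slide that held E11 and E12, 170 genes were at least 2-fold apart, 117 of them higher at E12, and within the slide that held E16 and E18, 238 were, 85 of them higher at E18. With scanner log ratios the counts were 4477, 1680 and 1702, and with median centring 2366 (34.4% higher at E18, against 70.1%), 391 (89.5% higher at E12, against 68.8%) and 659 (6.53% higher at E18, against 35.7%). With scanner log ratios 53.6% were higher between E18 and E11. Without background correction 261 genes were at least 2-fold apart between E12 and E11.

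Across genes, the log2 ratios of E11 and E12 correlated at r = 0.83 and those of E16 and E18 at r = 0.85, while E11 and E16 gave 0.23, E11 and E18 0.34, E12 and E16 0.16 and E12 and E18 0.20. Arrays that share a reference correlate without any effect: simulated unchanged stages gave between 0.497 and 0.506. Covariances were 0.187 for E11 and E12, 0.213 for E16 and E18, and between 0.0279 and 0.107 for the others. With the technical spread of E14 alone, simulated covariances were 0.00361 to 0.00396, which leaves out how far the E14 pool itself stood from other E14 pools. Genes are not independent replicates, and part of these correlations may come from the shared E14 pool and a shared dye effect. The highest were those of the pairs that shared a slide, E11 with E12 and E16 with E18. A slide effect on the Cy5 channel cannot be told apart from stage here, and the simulations held no slide effect.

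Which genes moved steadily through molar development was asked with a straight line in embryonic day over the 4 arrays. With a preset correlation between genes, the lists of dental epithelium factors (11 of 24 genes rose), odontoblast genes (9 of 22) and mesenchymal matrix (6 of 26) passed upward and those of erythroid genes (4 of 12 fell) and dental mesenchyme factors (11 of 24 fell) downward. None of these lists passed with an estimated correlation (adjusted p 0.524 to 0.536), a test with little power on 2 residual degrees of freedom. With slide as a block and the preset correlation, the odontoblast and matrix lists did not pass. All list p-values with slide as a block, here and below, use the preset correlation. They rest on 1 residual degree of freedom and measure spread over genes, not over pools, so a low one does not show that a list withstands slide. The largest rising slopes, in log2 units per day, were those of Serpinb5 (0.90 ± 0.13 SE), Sp6, a transcription factor of enamel-forming epithelium (0.90 ± 0.06), Kcnj8 (0.89 ± 0.10), the secreted Wnt inhibitor gene Wif1 (0.79 ± 0.07), Plac8 (0.78 ± 0.12), S100a14 (0.77 ± 0.10), Omd (0.76 ± 0.06) and S100a6 (0.75 ± 0.06), with adjusted p between 0.00520 and 0.0187. Sp6 was 56.4-fold higher at E18 than at E11. Omd was not well above background in Cy5 at E11 or E12, so its slope rests in part on floor values. The largest falling slopes were those of Hbb-y (-1.32 ± 0.09), Hbb-bh1 (-1.30 ± 0.13), Hba-x (-0.93 ± 0.09), Asb4 (-0.75 ± 0.06), Fgf8 (-0.65 ± 0.08), Prrx1 (-0.59 ± 0.04), the chemokine gene Cxcl12 (-0.57 ± 0.04) and Lhx8, a homeobox factor of jaw mesenchyme (-0.56 ± 0.04), with adjusted p between 0.00520 and 0.0108.

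In all 1550 of 17414 genes passed an adjusted p of 0.05, 1091 rising and 459 falling, and 4815 had an unadjusted p under 0.05. The residual has 2 degrees of freedom and holds array noise and curvature together, so a peak at E16 adds to it, although Serpinb5, Krt5, Col17a1 and Ibsp, all higher at E16 than at E18, passed. E11 and E12 lay on 1 slide and E16 and E18 on the other. The fit was therefore repeated with slide as a block, which leaves 1 residual degree of freedom. A blocked slope is set only by the steps within slides, and the longer step, from E16 to E18, weighs more. A blocked slope that is turned or near 0 can therefore come from that step, and does not by itself show a slide effect. In the blocked fit limma called 0 genes at an adjusted p of 0.05. An unadjusted p under 0.05 was reached by 582 of 17414 genes, a smaller share than the 0.05 that unchanged genes would give. Among the 1550 genes 1350 had a blocked slope of the same sign. The 1550 were chosen for lying near a straight line through the same arrays, which favours such agreement with the blocked fit. In that fit the slopes were 0.50 ± 0.17 for Sp6, 0.73 ± 0.17 for Shh, -0.62 ± 0.16 for Hbb-y, -0.61 ± 0.17 for Lhx8, 1.20 ± 0.33 for Plac8, -0.49 ± 0.17 for Prrx1, -0.45 ± 0.18 for Cxcl12, 0.38 ± 0.17 for Omd, 0.36 ± 0.17 for S100a6 and -0.33 ± 0.19 for Asb4. They were smaller, against their SE, for Wif1 (0.28 ± 0.18), Hbb-bh1 (-0.38 ± 0.24) and Hba-x (-0.23 ± 0.17), near 0 for Kcnj8 (0.034 ± 0.17), S100a14 (0.022 ± 0.21) and Fgf8 (-0.01 ± 0.17), and of the other sign for Serpinb5 (-0.11 ± 0.21). The count was 201 without the E11 array, 376 without E12, 2385 without E16 and 1986 without E18. Median centring gave 1240 genes, 40.6% of them rising against 70.4%.

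**Figure D2:**
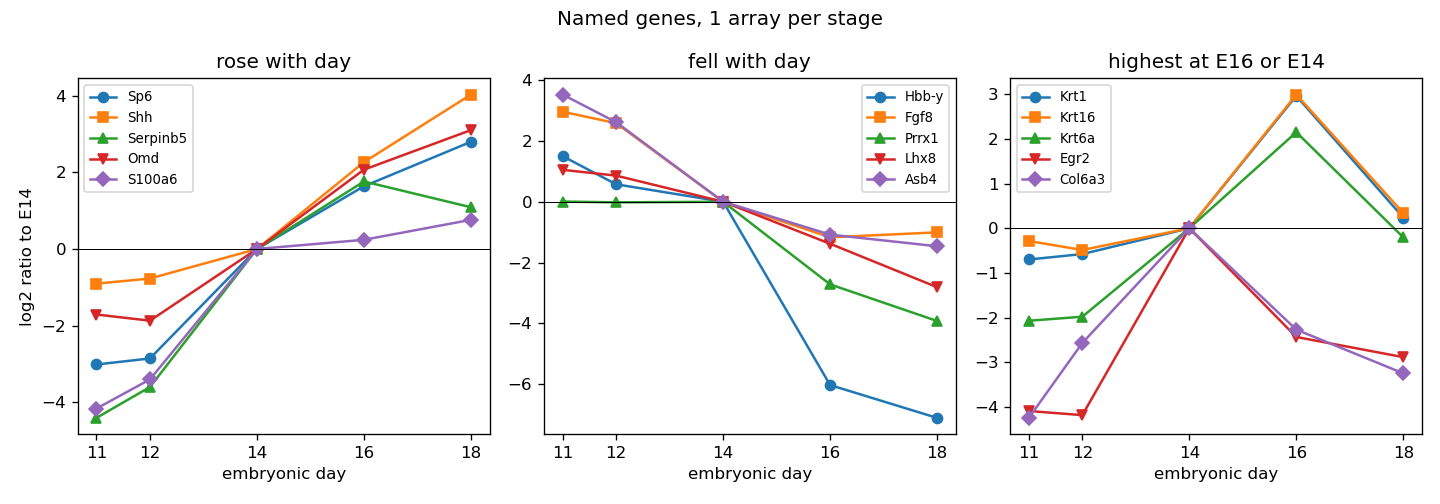
Log2 ratio to E14 (y axis) by embryonic day (x axis) for 5 genes that rose, 5 that fell and 5 that were highest at E16 or E14. Points are single arrays, E14 is at 0 by construction, and lines only join points. Sp6 went from -3.02 at E11 to 2.80 at E18, Hbb-y was at -7.11 at E18, and Krt1 was at 2.96 at E16 and at 0.24 at E18.

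The probes behind these values can be placed on the mouse genome build that the array file headers name, mm7. The Shh probe lies on chromosome 5 at 27489898 to 27489957, the Sp6 probe on chromosome 11 at 97133587 to 97133646, the Fgf8 probe on chromosome 19 at 45633777 to 45633836, the Prrx1 probe on chromosome 1 at 163209258 to 163209317 and the Hbb-y probe on chromosome 7 at 99909287 to 99909346. Whether each probe lies in a coding exon or a UTR was not analysed here.

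In both epithelial lists part of the genes rose. Of 29 epithelial keratins and junction genes, 16 rose, 1 fell and 12 did not pass (24 and 1 when adjusted over the list alone). Col17a1, a hemidesmosome collagen (0.63 ± 0.12), the basal keratin gene Krt5 (0.60 ± 0.10) and the plakophilin gene Pkp1 (0.60 ± 0.12, but -0.19 with slide as a block) had the largest slopes. Those of Col17a1 (0.0014 ± 0.29) and Krt5 (0.027 ± 0.21) were near 0 with slide as a block. Cdh1, or E-cadherin, rose (0.42 ± 0.06, adjusted p = 0.0158), Krt14 was at 0.31 ± 0.10 (adjusted p = 0.0983), and Cldn7 fell (-0.16 ± 0.04). Camera's adjusted p was 5.17e-09, and 0.524 with an estimated correlation. Median steps of its genes were 0.74 from E11 to E12 and -0.36 from E16 to E18. Its camera adjusted p with slide as a block was 0.674, upward in the test while the mean slope was -0.032. Of 24 dental epithelium factors and signals, 11 rose, 1 fell and 12 did not pass (13 and 1 over the list alone). Sp6 led, with Shh (0.73 ± 0.04) and Wnt10a, a Wnt ligand required for tooth number (0.64 ± 0.08, but 0.075 ± 0.18 with slide as a block), while Fgf8 fell. Edar, the ectodysplasin receptor gene, was at 0.25 ± 0.06 (adjusted p = 0.0539) and Sox2, an epithelial stem cell factor, at -0.17 ± 0.09 (adjusted p = 0.282). The list passed at a camera adjusted p of 2.75e-05, 0.524 with an estimated correlation and 0.0458 with slide as a block, with median steps of 0.43 from E11 to E12 and 0.02 from E16 to E18. Its median slope was 0.18, but -0.0015 with slide as a block, where the mean slope was 0.051. Shh was not well above background in Cy5 at E11, so its slope rests in part on a floor value.

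In the enamel list and the enamel knot list part of the genes rose. Of 12 measured ameloblast and enamel genes, 6 rose and none fell (9 and 0 over the list alone), with Sp6, Adgrf4 (0.52 ± 0.05) and Odam, an ameloblast-associated protein (0.45 ± 0.09), in front. Odam was not well above background in Cy5 at E11 or E12, so its slope rests in part on floor values. Camera gave an adjusted p of 7.81e-05, 0.4999 with an estimated correlation and 2.91e-05 with slide as a block, and the median steps were 0.20 (E12 over E11) and 0.49 (E18 over E16). The enamel matrix genes themselves did not pass: Ambn, or ameloblastin, was at 0.07 ± 0.04 and the brightest Amelx (amelogenin) probe at -0.01 ± 0.02. Ambn was at least 1.76-fold higher at E16 than at E14 and at least 1.12-fold higher at E18. A dimmer Amelx probe, well above background in Cy5 only at E16 and in the E14 channel on no array, was at least 2.48-fold higher at E16. Enam and Mmp20 were not well above background in any stage, and no probe was named Fgf4. Of 19 enamel knot genes, 7 rose and none fell (8 and 2 over the list alone), led by Shh, Wnt10a and Sostdc1, a BMP and Wnt inhibitor (0.64 ± 0.08), and Bmp4 was at 0.05 ± 0.03 (adjusted p = 0.388). For the enamel knot list the camera adjusted p was 0.00674, 0.524 with an estimated correlation and 0.361 with slide as a block (median steps 0.05 and -0.05).

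Among 22 odontoblast, dentin and bone genes 9 rose, 1 fell and 12 did not pass (9 and 1 over the list alone). Omd, Smpd3, a sphingomyelinase of mineralizing tissue (0.67 ± 0.04), and Alpl, the alkaline phosphatase of mineralization (0.64 ± 0.06), had the largest slopes. Ibsp, or bone sialoprotein (0.43 ± 0.09, adjusted p = 0.0377, with a slope of -0.31 with slide as a block), and Sp7, or osterix (0.27 ± 0.04, adjusted p = 0.0138), rose, and the parathyroid hormone receptor gene Pth1r fell (-0.25 ± 0.04). Neither Omd nor Ibsp was well above background in Cy5 at E11 or E12, so their slopes rest in part on floor values. Dspp, which encodes dentin proteins other than collagen, was well above background only at E16, where it was at least 2.33-fold higher than at E14. Dmp1, well above background in Cy5 only at E16, was at 0.75 there. Col1a1, the bone and dentin collagen, was at -3.51, -2.28, -0.41 and -1.74 from E11 to E18 (slope adjusted p = 0.160). As a list these genes had a camera adjusted p of 1.48e-04, 0.524 with an estimated correlation and 0.736 with slide as a block, where the mean slope turned to -0.039. Median steps were 0.19 from E11 to E12 and -0.26 from E16 to E18.

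Of 24 measured dental mesenchyme factors, 11 fell, 3 rose and 10 did not pass (14 and 4 over the list alone). Prrx1, Lhx8 and Lhx6, LIM and paired homeobox factors (-0.46 ± 0.05 for Lhx6), fell most. Pax9 (-0.39 ± 0.05, adjusted p = 0.0108), Msx1 (-0.31 ± 0.05, adjusted p = 0.0255) and Barx1, a molar-field factor (-0.25 ± 0.04, adjusted p = 0.0150), fell as well, while Msx2 (0.59 ± 0.07), Dlx2 (0.27 ± 0.03) and Tfap2a (0.16 ± 0.03) rose. For the list camera gave an adjusted p of 1.18e-04, 0.524 with an estimated correlation and 3.90e-07 with slide as a block, and the median steps were 0.02 from E11 to E12 and -0.54 from E16 to E18. Of 14 heterochronic and imprinted fetal growth genes, which are high in early embryos, 9 fell and none rose (11 and 0 over the list alone). Hmga2 (-0.50 ± 0.03), Dlk1 (-0.46 ± 0.03) and Igf2bp1 (-0.32 ± 0.03) were in front. Camera gave an adjusted p of 1.52e-08, 0.4999 with an estimated correlation and, with the preset one, 3.22e-16 with slide as a block. Median steps were -0.03 and -0.84, and the blocked p-value rests mainly on the second, between single pools.

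**Figure D3:**
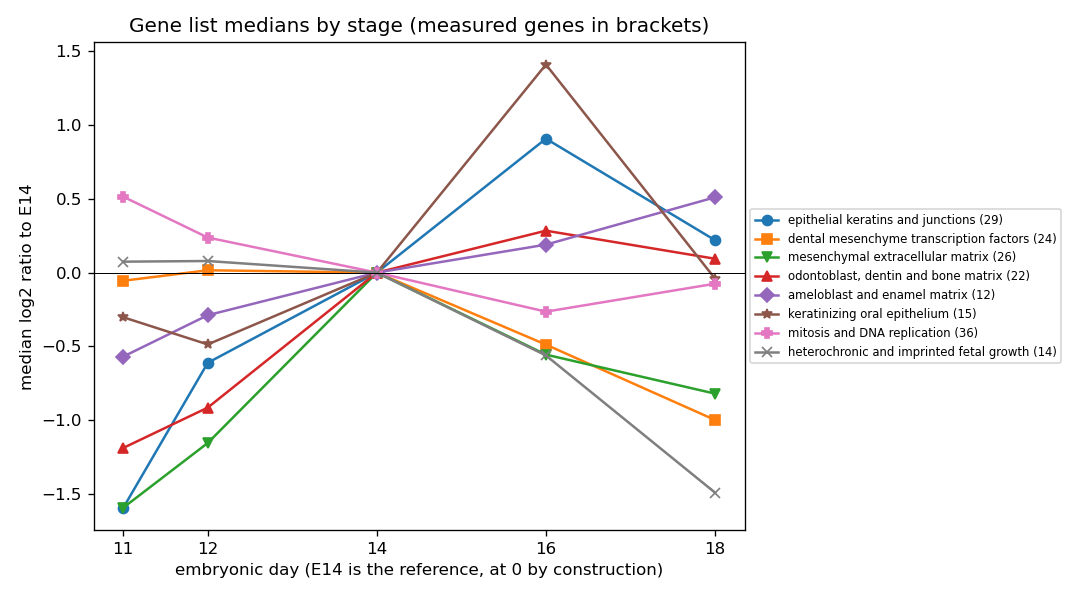
Median log2 ratio to E14 (y axis) of 8 gene lists by embryonic day (x axis), with 1 array per stage and E14 at 0 by construction. Epithelial keratins went from -1.59 at E11 to 0.91 at E16 and 0.22 at E18, dental mesenchyme factors from -0.06 at E11 to -0.49 at E16, and the keratinizing list was at 1.41 at E16 and -0.04 at E18.

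Of 36 mitosis and DNA replication genes 4 fell and none rose (14 and 0 over the list alone), with the cyclin gene Ccne1 (-0.23 ± 0.03) and the mitotic kinase gene Aurka (-0.16 ± 0.03) among those that fell, while Rrm2 was at -0.16 ± 0.04 (adjusted p = 0.0760), Mki67 was at -0.06 ± 0.04 and Top2a at -0.11 ± 0.04, none of them passing. Camera gave an adjusted p of 5.57e-07, 0.536 with an estimated correlation and 0.336 with slide as a block, where the mean slope turned to 0.023, and the median steps were -0.21 and 0.18. Mesenchymal matrix genes had medians of -1.59, -1.15, -0.56 and -0.82 from E11 to E18, below E14 on all 4 arrays, but with median centring the median at E16 was 0.38, where that of all genes was 0.57. By slope 6 of 26 rose and none fell (10 and 1 over the list alone), led by Ogn, or osteoglycin (0.72 ± 0.08), Col14a1 (0.54 ± 0.05) and Lum, or lumican (0.46 ± 0.04). Camera gave an adjusted p of 8.36e-04, 0.536 with an estimated correlation and 0.339 with slide as a block, where the mean slope turned to -0.042. Median steps were 0.47 and -0.34.

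Signalling lists moved in part. Among 15 BMP genes 4 rose and 1 fell (8 and 1 over the list alone), with Msx2, Bambi, a pseudoreceptor (0.55 ± 0.05), and Id4 (0.54 ± 0.03) rising, and camera gave an adjusted p of 4.86e-04 (0.4999 with an estimated correlation, 7.84e-04 with slide as a block, median steps 0.10 and 0.30). Among 13 Notch genes 4 rose and 1 fell (10 and 1 over the list alone), Jag2, a Notch ligand (0.22 ± 0.03), and Hey2 (0.19 ± 0.02) rising, Notch3 falling (-0.18 ± 0.04) and Heyl at 0.20 ± 0.05 (adjusted p = 0.0748), with an adjusted p of 5.86e-04 for the list (0.4999 with an estimated correlation, 0.0115 with slide as a block, median steps 0.08 and 0.17). Hey2 was not well above background in Cy5 at E11, nor in the E14 channel on the E18 array, so its slope rests in part on floor values. Hedgehog targets (adjusted p = 0.271), Wnt targets (0.230) and FGF genes (0.104) did not pass as lists. Of 6 hedgehog targets Ptch1 and Hhip rose (3 and 0 adjusted over the list alone), of 17 Wnt genes 5 rose and 2 fell (5 and 2), and of 15 FGF genes 3 rose and 1 fell (4 and 2). Among the Wnt genes Wif1 and Sostdc1 rose and Sfrp2 fell (-0.44 ± 0.08). With fry, which asks whether a list's own genes move one way, the ameloblast (adjusted p = 0.0277), BMP (0.0259), Notch (0.0277) and endothelium (0.0332) lists passed.

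Markers of other tissues that a pooled germ can hold moved in part. Of 12 erythroid genes 4 fell and none rose (8 and 1 over the list alone), namely Hbb-y, Hbb-bh1, Hba-x and Slc4a1, the red cell anion exchanger (-0.45 ± 0.04), while Hba-a1, an adult alpha globin, was at 0.13 ± 0.03 (adjusted p = 0.0596), and the camera adjusted p was 3.18e-04 (0.524 with an estimated correlation, 3.50e-04 with slide as a block, median steps -0.61 and -0.09). The keratinizing list passed (adjusted p = 0.00674, 0.686 with an estimated correlation) although only 1 of 15 members rose by itself, Lor, or loricrin (0.26 ± 0.04; 1 and 0 over the list alone). Krt13 was at 0.48 ± 0.12 (adjusted p = 0.0669). With slide as a block the mean slope of this list turned to -0.54 at a camera adjusted p of 1.32e-16, and its median steps were -0.06 and -1.21. That p-value is over genes that move together (estimated correlation 0.82), and not over pools. Of 10 osteoclast genes 5 rose and 1 fell (7 and 1 over the list alone), with Ctsk, the bone-resorbing protease (0.39 ± 0.04), and Mmp9 (0.37 ± 0.05) in front, at an adjusted p of 0.00441 (0.524 with an estimated correlation, 0.302 with slide as a block, median steps -0.06 and 0.11). Immediate early and heat shock genes passed (5 of 15 rose, 1 fell, 8 and 1 over the list alone, adjusted p = 0.00261, 0.657 with an estimated correlation). Hspa1a (0.47 ± 0.07, but -0.019 with slide as a block) and Junb (0.36 ± 0.05, but 0.012 ± 0.17 with slide as a block) led. The mean slope of this list turned to -0.10 with slide as a block, at an adjusted p of 0.00170 (median steps -0.09 and -0.15). Macrophage genes passed as well (adjusted p = 0.0386, 0.688 with an estimated correlation), of which Tyrobp, a myeloid adaptor, rose and Coro1a fell among 17 (3 and 1 over the list alone), with a blocked mean slope of -0.10 (adjusted p = 3.45e-04) and median steps of -0.18 and -0.17. Lists for endothelium (adjusted p = 0.189), skeletal muscle (0.766), cartilage (0.766), neurons (0.553), Schwann cells (0.791), liver (0.913) and Hox genes (0.418) did not pass. Among them 2 cartilage genes rose and 1 fell (3 and 3 over the list alone), 2 neuron genes rose, Tubb3 and Stmn2 (3 and 3), 2 Schwann cell genes rose, S100b and Mbp (2 and 1), and Hoxb3 fell (1 and 1), with 0 calls either way for endothelium, muscle and liver.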

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

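The tests of slide, of exchanged labels, of a dye effect and of handling were chosen after the values they bear on had been seen. The tests on a second epithelial list and on other probes were written before their result was seen.

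A dimmer probe of Amelx, which the choice of the brightest probe leaves out, read 1.42 (log2) at E16 over E14, while the probe used stayed at 0.10. The dimmer probe was well above background in Cy5 at E16 and at no other stage, and in the E14 channel on no array, so the value stands for a bound of at least 2.48-fold.

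Genes highest at E16 formed a set of 35, and 10 of them belong to the keratinizing oral epithelium list, fixed in advance, whose median step from E16 to E18 was -1.21. An exchange of the E16 and E18 labels is argued against by the heterochronic and imprinted list, which should be higher in the younger pool and had a median step of -0.84 from E16 to E18. Lists of the cells that differentiate late were split. The ameloblast list had a median step of 0.49 (3 genes 2-fold higher at E18, 1 lower). Odam (2.45), Adgrf4 (1.76) and Sp6 (1.16) were the 3 higher. The enamel matrix genes Ambn (-0.65) and Amelx (-0.27, brightest probe), both dim, were lower at E18 than at E16. The odontoblast list had one of -0.26 (1 higher, 3 lower, Dspp among them). An exchange is therefore not excluded. A fault of single probes is argued against by 11 other measured probes of 9 of the 35 genes, with a median of 0.60 higher at E16 than at E18. Of these probes 10 were above 0, and the other probe of Krt1, dim at both stages, was at -0.12. Sizes depended on the probe: Dmkn was at 0.15 against 1.76 for the probe used and Col4a6 at 0.43 and 0.18 against 2.08, while Krt13 was at 4.27 against 1.30. Genes without another measured probe could not be checked. Keratinizing epithelium carried along with the E16 pool may be the source: a second list of stratified epithelium genes (18 of 24 measured) was higher at E16 than at E18 in 18 of 18, but by a median of 0.36, below the 0.5 set for that reading, at percentile 100 of random lists, so the test does not decide. A change of the germ itself at E16 stays open, untested with 1 pool.

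Genes at least 2-fold lower than E14 on all 4 arrays numbered 61, Egr2, Egr1, Col6a3, Col6a2, Postn and Fgf18 among them, against Rspo2 and an unnamed clone that were 2-fold higher on all 4. With median centring 51 of the 61 stayed lower on all 4 arrays and 7 stayed 2-fold lower. Over 41 other probes of 25 of these genes the ratio nearest to E14 had a median of -0.47. Of these probes 36 were lower than E14 on all 4 arrays, and 7 were 2-fold lower on all 4. A dye effect shared by the probes of a gene would look the same. Because E14 was always in Cy3, a dye effect, as the whole size or part of it, cannot be told apart from a peak at the cap stage. Such a peak stays open. The median range of 0.74 between the 4 ratios of a gene does not bear on the dye. The other stages may differ among themselves whether or not the offset they share comes from the dye. Handling of the E14 pool, which would raise immediate early genes there, was to be excluded if that list stood above E14 on 1 array by more than 0.09: its median at E16 did (0.19), but handling of the E16 pool could raise it alike, so this bound was set wrongly, and handling cannot be told apart from the stage, since the medians at E11 and E12 lay below 0 and 3 members of the list are among the 61.

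Genes at least 2-fold apart between the mean of E16 and E18 and that of E11 and E12 numbered 1194, and the stages lay on separate slides. Slide alone would leave steps within a slide without direction, and 62.9% of these genes went the same way from E16 to E18 and 62.6% from E11 to E12. Of the 299 genes lower late 78.9% were lower at E18 than at E16 and 50.8% lower at E12 than at E11, and of the 895 genes higher late 57.5% were higher at E18 than at E16 and 66.6% higher at E12 than at E11, where 48.5% and 50.2% of all genes were higher at E18 and at E12. Choosing genes by slide means favours steps toward the more variable arrays, E18 and E11, and with genes chosen without that array the 78.9% became 60.4% of 222 genes (95% binomial interval 53.6% to 66.8%) and the 66.6% became 55.5% of 838, against a bound of 60% for excluding slide, while the 50.8% became 26.7% and the 57.5% became 41.5%. E14 lay on both slides: 5 to 8 genes were at least 2-fold apart between E14 hybridisations on different slides, against 5 and 7 on the same slide. That argues against slide, acting on the E14 channel, as the source of the 1194. Slide acting on Cy5 alone, wholly or in part, cannot be told apart from stage for either set. The stages before and after E14 lay on separate slides, no Cy5 sample was on both, and genes are not independent.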

How the results depend on the processing

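The count without the keratin lists was chosen after the data were seen. Counts of genes at least 2-fold apart depended most on how ratios were made. Scanner log ratios gave 3854 (E11), 2252 (E12), 2883 (E16), 4513 (E18), 4477 (E18 against E11), 1680 (E12 against E11) and 1702 (E18 against E16), and the values of the series table were 3843, 2245, 2878, 4502, 4473, 1676 and 1700. Both lack the added offset; the cause was not tested. Median centring, which leaves the intensity curve in, gave 4556, 5790, 4297, 2310, 2366, 391 and 659, and no background correction 261 for E12 against E11. Under the other alternatives these totals stayed within 1.5 times, but the 55 genes higher at E12 became 89 without background correction, 88 with scaling and 35 with the mean of probes, the 117 higher at E12 than at E11 became 184 without background correction and 73 with the mean of probes, the 85 higher at E18 than at E16 became 50 with scaling and 55 with probes well above background throughout, and the 295 lower at E16 became 465 without background correction. The trend count was 0 with slide as a block, where 1 residual degree of freedom remains, and between 201 and 2385 with 1 array left out. The other trend alternatives gave 1185 to 1986. Without the keratin lists it was 1566. Of 26 lists 16 passed with a preset correlation, 0 with an estimated one, which has 2 residual degrees of freedom, and 4 with fry. Slopes of Mmp9 (0.040 ± 0.16), Sp7 (0.077 ± 0.14) and Ogn (0.088 ± 0.17) were near 0 with slide as a block. Blocked slopes weigh the step from E16 to E18 most, so a step there against the trend can turn them with no slide effect. With slide as a block slopes turned for Serpinb5 (-0.11), Ibsp (-0.31), Pkp1 (-0.19), Hspa1a (-0.019) and S100b (-0.031), for genes that had not passed, Krt1 (-1.07), Krt16 (-1.10), Krt13 (-0.25), Egr2 (-0.20), Col6a3 (-0.056), Edar (-0.10), Krt14 (-0.043), Col1a1 (-0.29), Ambn (-0.19), Dspp (-0.45), Dmp1 (-0.32), Mki67 (0.17) and Top2a (0.020), and mean list slopes for epithelial keratins (-0.032), odontoblast (-0.039), matrix (-0.042), mitosis (0.023), keratinizing (-0.54), macrophage (-0.10) and immediate early genes (-0.10), and for Wnt (-0.080), cartilage (-0.028) and Schwann cell genes (-0.077), which had not passed. Median centring turned list medians at E12 for ameloblast (0.046), dental epithelium (0.59), keratins (0.076), Wnt (0.015), BMP (0.84), Notch (0.15) and endothelium (0.45), and at E16 for dental mesenchyme (0.29), matrix (0.38), mitosis (0.69), endothelium (0.18) and heterochronic genes (0.48). It moved the median of all genes as well, and relative to that 51 of 54 list medians that stood apart from random lists kept their sign, all but BMP at E12, mitosis at E16 and neuron at E11. With probes well above background in both channels of all 4 arrays the odontoblast median at E16 was -0.018 and the neuron median at E11 -0.14. Log2 ratios of the genes named as highest and lowest on each array, well above background in both channels, turned sign under none of the alternatives run. They were chosen for their large ratios, so a turn was unlikely and its absence shows little. Over these alternatives 181 of their values moved by more than the gene's SD of E14, and 130 did not. The log2 ratios of other genes named here, such as markers, list members, bounds and sex-linked genes, were not checked in this way. Signal over background limits the fold sizes of dim genes.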

Other observations

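The genes with a peak at 1 stage were read off after the values were seen. At E18, 73 genes were at least 2-fold above all other stages, led by Plac8 (margin 3.37), Pla2r1 (3.24), the gut peptide gene Pyy (3.12), Krtap17-1 (2.87) and Odam (2.45), with Car2, a carbonic anhydrase of osteoclasts and other cells (1.95), and Shh (1.77) further down. At E11, 24 genes were, among them Fabp7 (1.66), a glial and neural crest gene, Fli1 (1.57), of vessels and blood, the myeloid peroxidase gene Mpo (1.48), Meox2 (1.34), Tcf15 (1.33), Foxc2 (1.32) and Sox10, a neural crest factor (1.13). At E12 2 genes were, Cyp26b1 (1.17) and Cyp1b1 (1.14). The cartilage list did not pass, yet its members parted: Col2a1 was at 1.33 at E11 and -1.37 at E18, and Matn4 was at 2.78 at E18.

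Of the genes highest at E14 by this margin, Egr2 was higher by 2.43 than the nearest other stage, Egr3 by 1.99 and Egr1 by 1.64. Nr4a1 (1.04) and Arc (1.11) were higher at E14 as well, while Fos was 0.93 and Jun 0.80 higher at E16 than at E14. No enrichment of a gene class was tested in this set, which held 3 of 15 genes of the immediate early and heat shock list. Others in it were Col6a3 (2.27), Prelp (2.16), Col6a2 (1.53) and Timp1, a metalloprotease inhibitor (1.45).

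The sex of the pooled embryos is not given in the sources used here, and sex-linked genes, chosen after their values were seen, differed between pools. The Y-linked genes Ddx3y and Eif2s3y were not well above background in Cy5 at E18, where they were at least 3.04-fold and 2.21-fold lower than at E14, and at E11 they were at 0.44 and 0.70. Xist was at -1.84 at E11, -0.81 at E12, -0.37 at E16 and -0.13 at E18, and Erdr1, a gene of the sex chromosomes, at -1.53, -1.57, -1.38 and -3.72. Differences between stages therefore include any difference in sex between the pools, which was not tested.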
